A study of Mus musculus with 6 samples.

How the data were processed

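Kidneys of wild-type (WT) mice and of mice labelled Lpar3-/-, which are described as lacking lysophosphatidic acid (LPA) receptor 3, were profiled by RNA sequencing after 12 h in a normobaric chamber at 8% oxygen. Each group had 3 libraries. All were hypoxic, and kidneys kept in normal air were not analysed here, so the comparison is between genotypes under hypoxia and cannot show a response to hypoxia. Per the labels' protocols, total RNA was extracted by a CTAB method, polyadenylated RNA was captured on poly-T beads and fragmented, and cDNA was made with random hexamers.

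The deposited counts are whole numbers of reads per gene, not normalized, with 1 column per library. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used with the genome build GRCm38. The strand setting, the annotation release and the treatment of reads that fit several genes are not given in the sources used here. Reads from overlapping genes, or from near-identical copies, may therefore have been split, dropped or given to one gene, and counts of such genes are less certain. The second deposited table holds FPKM values made by the authors. Recomputed from the counts over genes with at least 20 counts, these FPKM values equalled the counts divided by gene length and by an effective library size, the median-of-ratios size factor times the geometric mean of the totals. The largest relative deviation was 4.11e-08. The FPKM table therefore holds no measurement beyond the counts and served for an alternative test.

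The count table had 54909 rows. Of these, 377 had no gene name and held 0.259% to 0.362% of the counts of a library. They were left out of library sizes and tests, which left 54532 named genes. Total counts ran from 16011804 to 17991881 per library, and the mitochondrially encoded genes took 6.80% to 7.97% of them. No library was a copy of another: the chi-square statistic of the counts per degree of freedom ran from 13.0 to 13.9 for pairs within WT, from 4.44 to 7.66 for pairs labelled Lpar3-/- and from 8.34 to 17.3 between the groups, where sampling noise alone gives about 1.

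Groups and replicate numbers were taken from the sample titles. The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with all 6 libraries, no covariate, the default expression filter for the 2 groups, TMM normalization and Benjamini-Hochberg adjustment over the 15225 genes tested. Genes with an adjusted p below 0.05 are called. Log2 fold changes are the libraries labelled Lpar3-/- over WT. Standard errors (SE) were derived from the fold change and the F statistic, and intervals are 95% intervals. Expression levels in CPM, counts scaled to the same total, use TMM-scaled library sizes and are given as mean ± SD. Between replicates, the common dispersion corresponded to a coefficient of variation of 10.5%.

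Before the data were examined, 43 gene lists were fixed, 18 of pathways, 17 of cell types and other tissues the samples could hold, and 8 of technical or sex- and strain-related genes. The 42 with at least 3 genes tested were compared with all other genes by camera (limma 3.58.1, voom values, preset correlation 0.01, two-sided), adjusted by Benjamini-Hochberg over the lists. Camera with an estimated correlation between the genes of a list and the directional fry test were alternatives. The former also takes its p from the 4 residual degrees of freedom, so it is stricter even where genes do not move together. Genes were named by a rule fixed at the same time. It took Lpar3, Epo and the other LPA receptors tested. It took the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 1 and groups that did not overlap, leaving out predicted and clone-named genes. It took up to 4 members with the lowest p of each list described, and up to 6 called genes within 20 Mb of Lpar3. Called genes within 20 Mb of Lpar3 were counted against those elsewhere by Fisher's exact test, two-sided.

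The alternatives were DESeq2 1.42.0, limma-voom, other normalizations (RLE and upper quartile), no filter and a stricter filter (at least 10 counts in 3 libraries and a mean CPM of at least 1), the replicate number as a block, each library left out in turn, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.1. A fold threshold, protein-coding genes alone and other windows around Lpar3 were also tried. Chosen only after seeing the data were keeping the rows without a name, the level of an adipose marker list as a covariate, and leaving Epo out of the hypoxia list.

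The tests were run on simulated data first, with counts drawn from the means, dispersions and library sizes of these libraries. Over 15015 simulated genes, the edgeR test recovered 52.2% of genes changed 1.5-fold, 77.3% of those changed 2-fold and 93.8% of those changed 4-fold. Of its 161 calls, 9 (5.59%) were false. Camera called 0 of 42 random lists. The simulated genes were drawn independently of each other, so this cannot show how camera behaves when the genes of a list move together. Gene positions are those of the deposited table. They were compared with the GENCODE M21 annotation, also on GRCm38: 54409 of the 54909 gene identifiers were found there, 98.3% of them at the same coordinates. Exon overlaps were read from that annotation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.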

Results

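To investigate the role of LPA receptor 3 in the hypoxic kidney, gene expression was compared between mice labelled WT and mice labelled Lpar3-/- that had spent 12 h at 8% oxygen, a strong systemic hypoxia. The receptor binds lysophosphatidic acid, a signalling lipid, and the title of the series names the production of erythropoietin, the hormone that drives red cell formation, as the outcome. Kidney mRNA was sequenced in 3 libraries per group. The WT libraries held 17991881, 17208823 and 16011804 counts for replicates 1 to 3, and the libraries labelled Lpar3-/- held 17789664, 16032392 and 17323774. By the chi-square statistic of the counts per degree of freedom, WT replicate 1 was nearer to each library labelled Lpar3-/- (8.34 to 9.57) than to WT replicate 3 or WT replicate 2 (13.9 for the latter). The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may in part be technical.

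Lpar3 itself was expressed at the same level in both groups. The gene (ENSMUSG00000036832, GRCm38 chromosome 3, 146220963 to 146286186, plus strand, 3 exons) had 645, 634 and 577 counts in the WT libraries and 672, 592 and 580 in the libraries labelled Lpar3-/-. Its level was 36.3 ± 1.31 CPM against 36.4 ± 2.51 CPM (SD, n = 3 each). The log2 fold change was 0.0033 with an SE of 0.081 and a 95% interval of -0.17 to 0.18 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.997). The counts are given per gene, not per exon, and the sources used here do not say which part of the gene was altered, so they cannot show whether a deleted exon was missing. As the counts do not set the groups apart at the targeted gene, the second group is called the libraries labelled Lpar3-/- throughout, and every direction given here rests on the labels.

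The other LPA receptors did not pass the test. Lpar2 (18.7 ± 1.73 against 20.1 ± 1.30 CPM), Lpar6 (13.5 ± 0.580 against 12.2 ± 2.63 CPM), Lpar1 (5.37 ± 1.86 against 5.90 ± 0.991 CPM) and Lpar4 (1.24 ± 0.543 against 1.11 ± 0.384 CPM) had log2 fold changes of 0.10, -0.15, 0.14 and -0.16. An exon of Lpar6 overlaps one of Rb1. Lpar5 had 4 counts or fewer in each library and was not tested. Among the 12 tested genes of LPA receptors and LPA metabolism, edgeR called 0 over all genes and 0 adjusted over the list alone, DESeq2 and limma-voom each called 0, and 1 had an unadjusted p under 0.05. That gene was Enpp2, which encodes autotaxin, the enzyme that makes extracellular LPA (624 ± 38.2 against 528 ± 19.3 CPM, log2 fold change -0.24, SE 0.074). The list did not differ from other genes (camera, adjusted p = 0.705).

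Epo, which encodes erythropoietin, was 3.42-fold lower in the libraries labelled Lpar3-/-. It had 69, 57 and 61 counts in the WT libraries against 20, 15 and 19, or 3.65 ± 0.263 against 1.06 ± 0.102 CPM (SD, n = 3 each). The log2 fold change was -1.77 (SE 0.26, 95% interval -2.34 to -1.21), with an adjusted p of 0.0136 over all genes and 0.000726 adjusted over the list alone of hypoxia-inducible genes (edgeR quasi-likelihood, Benjamini-Hochberg). The difference is larger than the spread between replicates, although it rests on 187 counts in one group and 54 in the other. Epo (ENSMUSG00000029711, chromosome 5, 137483020 to 137533242, minus strand) spans several other genes. An exon among its 3 transcript models overlaps an exon of Gnb2, so some uncertainty in the assignment of reads remains. Without any one of the libraries labelled Lpar3-/-, the fold change stayed between -1.83 and -1.70 but the adjusted p rose above the threshold, to 0.0711 without replicate 1, 0.0777 without replicate 2 and 0.0922 without replicate 3 (edgeR quasi-likelihood).

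**Figure D1:**
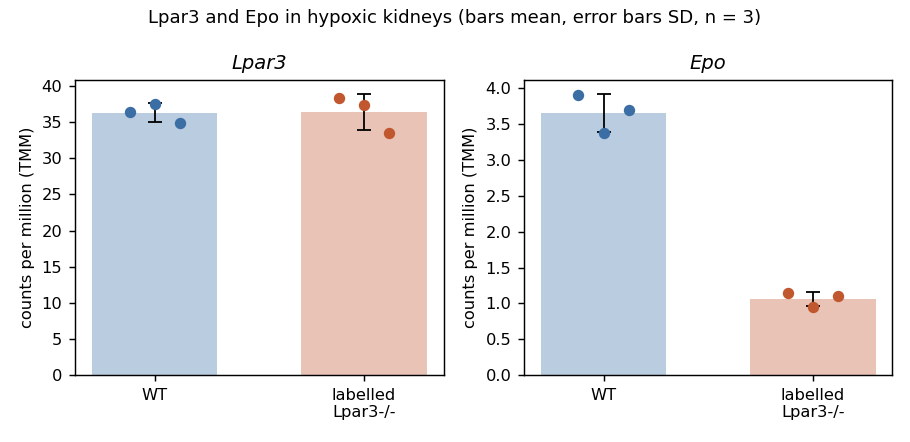
Expression of Lpar3 (left) and Epo (right) in CPM per library, for the WT libraries and those labelled Lpar3-/- (n = 3 each). Points are libraries, bars means and error bars SD, and Lpar3 lies at 36.3 and 36.4 CPM on average, and Epo at 3.65 and 1.06 CPM with no overlap between the groups.

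Across all genes, 57 of the 15225 tested differed between the groups, 19 higher and 38 lower in the libraries labelled Lpar3-/- (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and 1398 had an unadjusted p under 0.05. Of the 57, 54 were protein coding, and 9 of the higher and 11 of the lower genes changed at least 2-fold. In all 57 the 3 libraries of one group lay above the 3 of the other. That also held for 2086 tested genes (13.7%), where chance gives 10% for 3 against 3.

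The genes with the largest rises had varied functions. Slc7a12, an amino acid transporter gene, rose 4.15-fold (5.28 ± 0.927 to 21.9 ± 5.40 CPM), and Prlr, the prolactin receptor gene, rose 3.60-fold (18.4 ± 2.60 to 66.3 ± 9.96 CPM). Cyp27b1, which encodes the enzyme that makes active vitamin D, rose 2.85-fold (23.9 ± 5.93 to 68.0 ± 10.2 CPM). Dpys, which encodes an enzyme of pyrimidine breakdown, was 2.59-fold higher, Gpt (alanine aminotransferase) 2.29-fold and Kynu (kynureninase) 2.01-fold. Serpinc1, which encodes antithrombin, was 2.38-fold higher and Hsd17b14 1.93-fold. Pigr, the receptor that carries immunoglobulin A across epithelia, was 1.62-fold higher and reached 1252 ± 94.5 CPM. Cyp2a5 was 2.26-fold higher, but it has a close paralog, Cyp2a4, with which reads may be shared. Adjusted p-values of these 10 genes ran from 2.76e-05 for Prlr and Cyp2a5 to 0.0162 for Hsd17b14 (edgeR quasi-likelihood).

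The genes with the largest falls included collagens, enzymes and a transporter. Col8a1, a collagen of basement membranes and vessel walls, had the lowest p of all genes and fell 4.46-fold (30.6 ± 2.53 to 6.86 ± 0.228 CPM, log2 fold change -2.16, SE 0.11, edgeR adjusted p = 3.85e-06). Col27a1 was 2.44-fold and Col6a6 2.04-fold lower. Synpr, a synaptic vesicle protein gene, was nearly lost, with 35, 73 and 100 counts in WT against 2, 7 and 0. Maob (monoamine oxidase B, 2.43-fold), Il34 (a ligand of the macrophage growth factor receptor, 2.28-fold), Bag2 (a chaperone cofactor, 2.12-fold), Slco1a1 (an organic anion transporter, 2.01-fold) and Cyp7b1 (an oxysterol hydroxylase, 1.95-fold) were also lower. The adjusted p-values of these genes and Epo were at most 0.0421 (edgeR quasi-likelihood). Exons of Prlr, Serpinc1, Col6a6, Bag2 and Il34 overlap those of another annotated gene.

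Fits with a library left out have fewer libraries to test with, and none changed the sign of a called gene. Between these fits the count of 57 varied. It was 149 without WT replicate 1, 26 without labelled Lpar3-/- replicate 2 and 12 without either replicate 1 or replicate 3 of the libraries labelled Lpar3-/-, whereas DESeq2 called 171 genes and limma on log2(FPKM + 1) called 9. Of 22 called genes, namely Epo, the genes with the largest changes and the called neighbours of Lpar3, 8 passed in each of the 6 fits with 1 library left out, namely Slc7a12, Prlr, Cyp27b1, Gpt, Cyp2a5, Col8a1, Col6a6 and Lmo4. The other 14 all lost the call without labelled Lpar3-/- replicate 1, with edgeR adjusted p from 0.0578 (Col27a1) to 0.192 (Il34). All of them but Slco1a1 also lost it without replicate 3, from 0.0717 (Serpinc1) to 0.250 (Il34), and some without replicate 2, from 0.0513 (Cyp7b1) to 0.163 (Il34). Without WT replicate 3, Synpr, Il34 and Cyp7b1 lost it (edgeR adjusted p = 0.0553, 0.0735 and 0.0829).

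**Figure D2:**
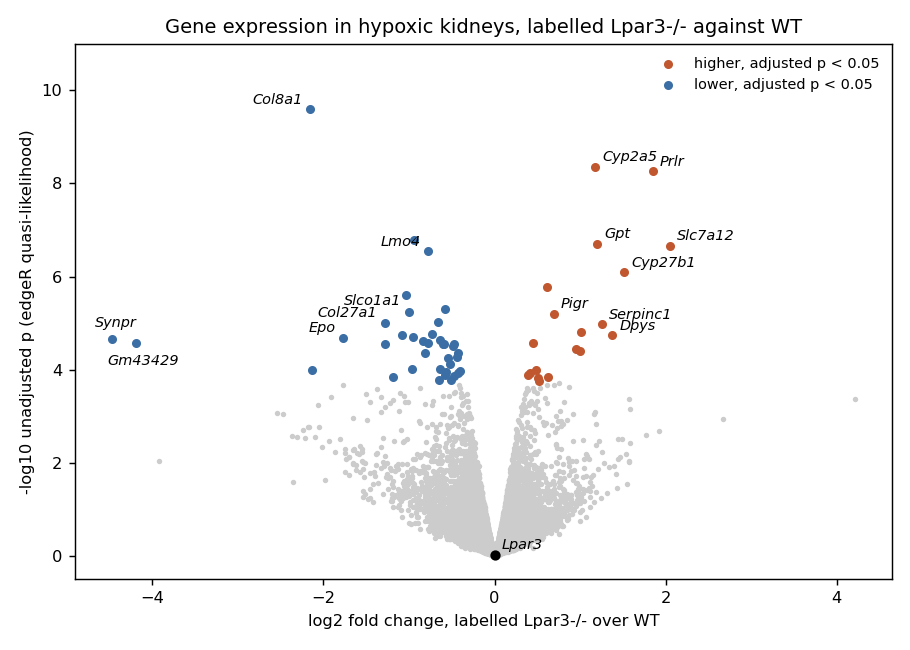
Log2 fold change (labelled Lpar3-/- over WT) against -log10 of the unadjusted edgeR p for the 15225 genes tested, each point a gene. Coloured points are the 19 higher and 38 lower genes that passed the adjusted threshold, and the black point is Lpar3, at 0.0033.

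Hypoxia-inducible genes were lower as a group in the libraries labelled Lpar3-/-, with the direction taken from the labels. Of the 35 targets of the hypoxia-inducible factors tested, 29 had a negative fold change, with a median of -0.15. Epo and Hmox1 (heme oxygenase 1, 71.7 ± 7.99 to 50.5 ± 4.09 CPM, log2 fold change -0.51, edgeR adjusted p = 0.0462) fell over all genes, but the call of Hmox1 was lost without WT replicate 2 (0.0779) or 3 (0.141) or labelled Lpar3-/- replicate 1 (0.108), 2 (0.181) or 3 (0.287), and that of Epo without any of the latter (0.0711, 0.0777 and 0.0922). In all, 7 fell adjusted over the list alone. Among the latter were Kdm3a, a histone demethylase (46.2 ± 1.70 to 35.9 ± 1.36 CPM), and P4ha1, a collagen prolyl hydroxylase (56.1 ± 2.89 to 42.6 ± 4.88 CPM). The list ranked below other genes (camera, adjusted p = 1.18e-06), and also without Epo (28 of 34 negative, adjusted p = 5.74e-06), a fit chosen after seeing the data. The adjusted p was 0.278 with an estimated correlation, and 0.306 without Epo.

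Glycolytic enzymes, a list that shares Ldha, Hk2 and Pgk1 with the hypoxia-inducible genes, also ranked low, with 13 of 16 negative and a median log2 fold change of -0.13 (camera, adjusted p = 0.00227, and adjusted p = 0.624 with an estimated correlation). Over all genes edgeR called 0 of them, DESeq2 called 1 and limma-voom 0, and 6 had an unadjusted p under 0.05. Adjusted over the list alone, Gapdh and Ldha (lactate dehydrogenase A) were lower. Ldha had 991 ± 56.3 against 791 ± 32.2 CPM, while Gapdh (49.7 ± 36.4 against 8.53 ± 0.479 CPM) varied widely within WT and has many processed copies in the genome, so its counts are uncertain. The fourth gene by p, Eno2, had a log2 fold change of -0.72 (SE 0.28), and the third, Aldoc, one of 0.42 (SE 0.15). Without WT replicate 1 the list did not pass (camera, adjusted p = 0.0840).

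The genes that sense oxygen or regulate Epo transcription did not shift as a group (camera, adjusted p = 0.298). EdgeR called 0 of the 17 over all genes, DESeq2 1 and limma-voom 0, with 2 at an unadjusted p under 0.05. Those were Kdm3a and Cited2, a partner of the coactivators of hypoxia signalling (114 ± 4.30 against 97.2 ± 2.95 CPM), which both passed adjusted over the list alone. The median of the 14 tested iron handling genes was 0.042 but their mean -0.061, and the list did not pass (camera, down, adjusted p = 0.903). In it Hmox1 fell over all genes. Adjusted over the list alone, Lcn2 was lower as well (7.50 ± 2.78 against 4.14 ± 0.927 CPM) and Ireb2 higher (151 ± 3.49 against 174 ± 4.54 CPM).

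**Figure D3:**
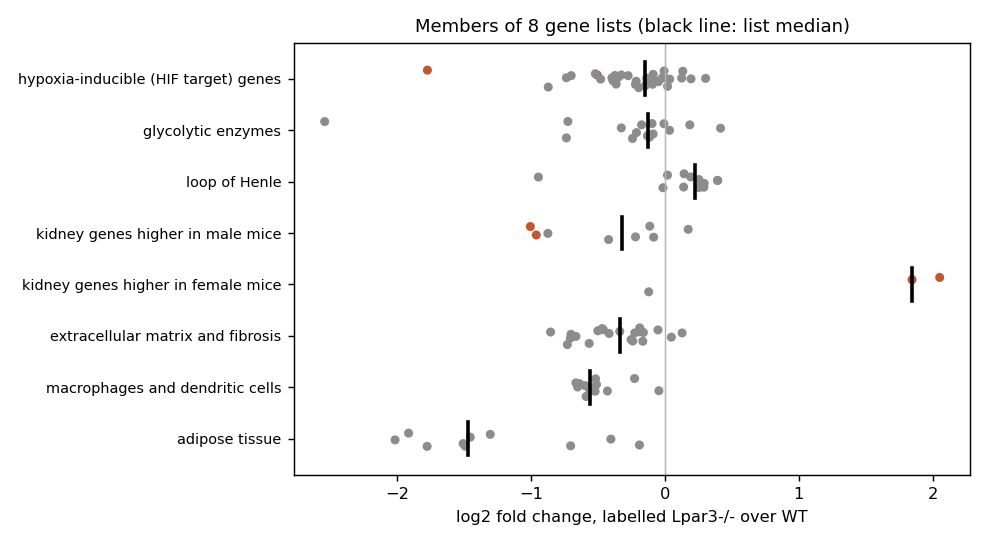
Log2 fold changes (labelled Lpar3-/- over WT) of the tested members of 8 gene lists, each point a gene, each black line the list median and each orange point a gene past the edgeR threshold over all genes. The medians run from -1.47 for adipose tissue to 1.85 for kidney genes higher in female mice.

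Genes of the loop of Henle, where salt is reabsorbed and urine concentrated, were slightly higher in the libraries labelled Lpar3-/-. Of the 12 tested, 10 had a positive fold change, with a median of 0.22. Slc12a1, the target of loop diuretics, had 1087 ± 74.1 against 1429 ± 64.1 CPM, Egf 1376 ± 114 against 1686 ± 31.7 CPM, Aqp1 982 ± 24.0 against 1172 ± 26.6 CPM and Cldn19 25.2 ± 1.81 against 30.8 ± 1.86 CPM. These and Cldn10, which lies outside the naming rule, made up the 5 that rose adjusted over the list alone. Of these, Egf lies 16.5 Mb upstream of Lpar3, inside the window whose genes are compared with all others below. EdgeR called 0 over all genes, DESeq2 3 and limma-voom 1, and 7 had an unadjusted p under 0.05. The list ranked above other genes (camera, adjusted p = 5.74e-06, and adjusted p = 0.173 with an estimated correlation), and it was 1 of the 2 lists past the threshold by fry, which asks whether the genes of a list move one way on balance and makes no comparison with other genes (adjusted p = 0.0279).

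Proximal tubule markers went both ways. Of the 14 markers of segments 1 and 2, adjusted over the list alone, Slc5a12 (817 ± 111 to 1064 ± 25.8 CPM) and Slc6a19 (533 ± 24.1 to 628 ± 33.9 CPM) were higher, and Slc5a2, the main glucose reabsorber (333 ± 12.4 to 270 ± 36.4 CPM), and Slc34a3 (68.2 ± 2.55 to 57.8 ± 4.19 CPM) were lower. EdgeR called 0 of them over all genes, DESeq2 1 and limma-voom 0, with 5 at an unadjusted p under 0.05, and the list did not pass (camera, adjusted p = 0.948). Of the 10 segment 3 markers, Slc22a7 was lower adjusted over the list alone (99.9 ± 46.5 against 46.9 ± 8.49 CPM), but 6 had a positive fold change. Their median was 0.048 and their mean -0.081, and the list did not pass (camera, up, adjusted p = 0.686).

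Most of the listed kidney genes known to differ between the sexes shifted towards the female pattern in the libraries labelled Lpar3-/-. Of 8 genes higher in male mice, 7 had a negative fold change, and Slco1a1 (441 ± 61.8 to 220 ± 38.8 CPM) and Cyp7b1 (log2 fold change -0.96, SE 0.17) fell over all genes. Adjusted over the list alone 4 fell, the others being Acsm3 (309 ± 73.3 to 169 ± 34.4 CPM) and Slc22a30 (103 ± 19.8 to 76.9 ± 6.83 CPM). Of 3 genes higher in female mice, Prlr and Slc7a12 rose, over all genes and adjusted over the list alone, while Cyp4a14 had 2894 ± 679 against 2661 ± 644 CPM. The calls of Cyp7b1 and Slco1a1 did not hold without labelled Lpar3-/- replicate 1 (edgeR adjusted p = 0.187 and 0.0612). The male list ranked below other genes (camera, adjusted p = 1.34e-05, and adjusted p = 0.624 with an estimated correlation). The female list ranked above them (camera, adjusted p = 1.24e-05, and adjusted p = 0.173 with an estimated correlation). By fry, which makes no comparison with other genes, its adjusted p was 0.0279. Y-linked genes were expressed in all 6 libraries, at similar levels in both groups, as with Ddx3y (68.0 ± 4.76 against 66.4 ± 6.11 CPM), and Xist had 5 counts or fewer in each.

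Matrix, immune and injury genes were lower on average in the libraries labelled Lpar3-/-, a direction that again rests on the labels. Of 21 matrix and fibrosis genes, 19 had a negative fold change, with a median of -0.34. Acta2 (25.2 ± 0.816 to 18.2 ± 2.71 CPM), Loxl1 (12.1 ± 3.79 to 7.45 ± 0.706 CPM), Col6a1 (21.5 ± 7.17 to 13.5 ± 1.19 CPM), Lox (19.6 ± 4.06 to 13.8 ± 1.37 CPM) and Col3a1, the last named outside the rule, were the 5 lower adjusted over the list alone. All 14 macrophage and dendritic cell genes had negative fold changes, with a median of -0.56, and the complement genes C1qa (16.2 ± 2.67 to 11.1 ± 0.359 CPM) and C1qc (11.1 ± 2.94 to 7.08 ± 0.558 CPM) were the 2 lower adjusted over the list alone. EdgeR, DESeq2 and limma-voom each called 0 members of these 2 lists over all genes, while 8 and 5 had an unadjusted p under 0.05. Camera placed both below other genes (adjusted p = 3.98e-06 and 1.27e-05, with adjusted p = 0.624 for each with an estimated correlation).

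Inflammatory mediators and markers of tubular injury had medians of -0.49 over 13 and -0.30 over 17 genes (camera, adjusted p = 0.00481 for each, and adjusted p = 0.721 and 0.624 with an estimated correlation). Il34 was the only inflammatory gene to fall, over all genes and adjusted over the list alone, and Ccl5 (3.12 ± 2.73 against 0.933 ± 0.270 CPM) and Vcam1 (21.6 ± 21.2 against 8.22 ± 0.963 CPM) varied widely within WT. Of the injury genes edgeR, DESeq2 and limma-voom called 0 over all genes, with 8 at an unadjusted p under 0.05, and Krt20, Sox4, Lcn2 and Vim were lower adjusted over the list alone. WT replicate 2 stood apart in these groups. Its mean list level, as log2 difference from the mean of the 6 libraries, was 0.88 for inflammation, 0.79 for macrophages, 0.58 for injury and 0.47 for matrix, where the other libraries ran from -0.35 to 0.22. WT replicate 1 lay within the range of the libraries labelled Lpar3-/- for matrix (-0.20 against -0.25 to -0.083) and inflammation (-0.19 against -0.32 to -0.16). For macrophages (-0.032) and injury (-0.096) it lay above them (at most -0.14 for each). Without WT replicate 2 the inflammation and injury lists did not pass (camera, adjusted p = 0.207 and 0.261), while the matrix and macrophage lists did (0.00333 and 0.0426).

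Adipose tissue markers showed the largest median shift among the lists that fell. All 10 tested had negative fold changes, with a median of -1.47 (camera, adjusted p = 4.80e-11, and adjusted p = 0.559 with an estimated correlation). Car3 (log2 fold change -1.45), Cfd (59.3 ± 21.6 against 15.9 ± 11.6 CPM), Cidec (23.7 ± 8.48 against 6.98 ± 4.10 CPM) and Plin1 (8.19 ± 2.42 against 2.90 ± 1.31 CPM) were among the 6 lower adjusted over the list alone. Over all genes edgeR called 0, DESeq2 3 and limma-voom 0, with 9 at an unadjusted p under 0.05. The list level overlapped little between groups and varied widely within them, at 1.19, 0.73 and 0.058 in WT replicates 1 to 3 and -0.96, 0.096 and -1.12 in replicates 1 to 3 labelled Lpar3-/-.

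**Figure D4:**
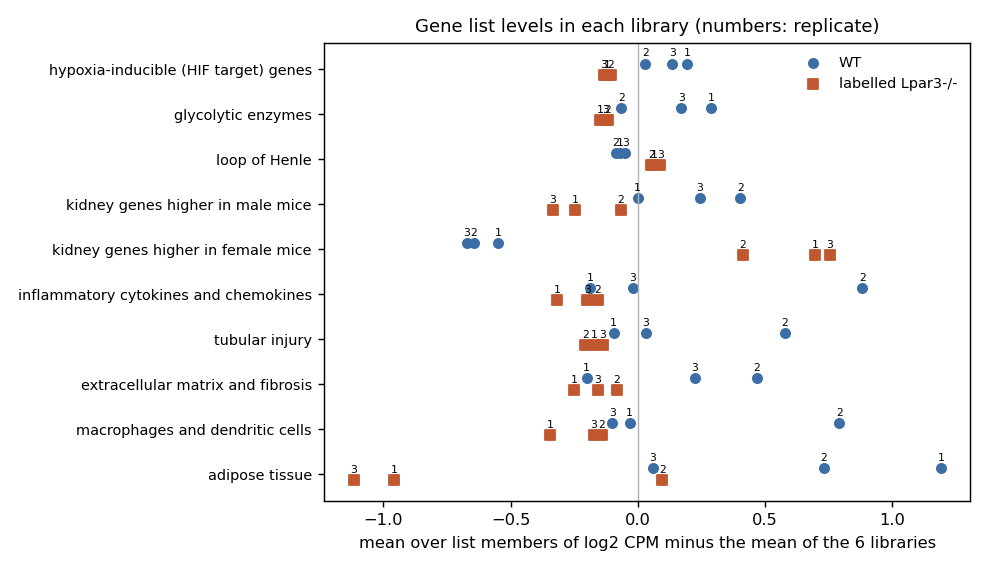
Mean level of 10 gene lists in each library, as log2 CPM minus the mean of the 6 libraries, averaged over the members of the list, with circles for WT libraries, squares for those labelled Lpar3-/- and numbers for replicates. WT replicate 2 lies at 0.88 for inflammatory genes, and adipose markers spread from -1.12 to 1.19.

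Camera with the preset correlation also called 8 more lists. Genes of the unfolded protein response (18 of 20 negative, median -0.12), interferon response (17 of 23, -0.18), cell cycle (16 of 22, -0.24), interstitial fibroblasts and pericytes (13 of 15, -0.19) and immediate early response (11 of 15, -0.26) ranked low, with camera adjusted p = 0.000507, 0.0320, 0.0437, 0.0268 and 0.0457. Nuclear oxidative phosphorylation genes (24 of 26 positive, median 0.060), cytoplasmic ribosomal proteins (25 of 28, 0.067) and mitochondrially encoded genes (10 of 13, 0.10) ranked high, with camera adjusted p = 0.00791, 0.0132 and 0.0481. With an estimated correlation the adjusted p was 0.624 for the unfolded protein response and 0.726 for the other 7. EdgeR, DESeq2 and limma-voom called 0 members of these lists over all genes, and edgeR 0 adjusted over the list alone, with 5, 4, 2, 3, 3, 0, 0 and 1 at an unadjusted p under 0.05 in the order given. Apart from the unfolded protein response, each call was lost without 1 or more single libraries. Without WT replicate 2, adjusted p = 0.639 for interferon and cell cycle, 0.969 for fibroblasts, 0.677 for immediate early and 0.653 for mitochondrially encoded genes, and without WT replicate 3, 0.562 for oxidative phosphorylation and 0.750 for ribosomal proteins (camera). The fibroblast and ribosomal lists changed direction in these fits. WT replicate 3 also ended the calls of fibroblasts (0.0756), immediate early (0.0609) and mitochondrially encoded genes (0.0510) when left out. Leaving out labelled Lpar3-/- replicate 1 ended those of interferon (0.702), cell cycle (0.141), immediate early (0.0941), oxidative phosphorylation (0.144) and ribosomal genes (0.0630), replicate 2 those of cell cycle (0.0867) and immediate early genes (0.227), and replicate 3 those of fibroblasts (0.110) and mitochondrially encoded genes (0.279).

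In total 18 of the 42 lists passed camera with the preset correlation, 5 up and 13 down. With an estimated correlation 0 passed, with 3 at an unadjusted p under 0.05, and by fry 2 did. The 24 lists that did not pass, with adjusted p from 0.0523 for lymphocytes to 0.949 for podocytes, held markers of endothelium, collecting duct, distal tubule, smooth muscle and blood among others. The adrenal list had 2 tested genes, too few for a test. In them, Bhlhe40 of the clock list fell over all genes (63.1 ± 8.58 to 42.2 ± 3.74 CPM, edgeR adjusted p = 0.0405), though an exon of it overlaps one of another annotated gene. Its call was kept only without WT replicate 1, and its edgeR adjusted p was 0.0609 and 0.123 without WT replicates 2 and 3 and 0.0890, 0.197 and 0.260 without labelled Lpar3-/- replicates 1 to 3. Adjusted over the list alone, Ace of the renin-angiotensin list was lower (249 ± 31.8 against 180 ± 7.52 CPM), and Aqp4 of the collecting duct principal cells higher (67.5 ± 12.7 against 102 ± 19.6 CPM).

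To ask whether sequence around the targeted locus differed between the groups, as it can when an allele carries flanking sequence of another strain, genes within 20 Mb of Lpar3 were compared with all others. Of the 144 tested there, 2 (1.39%) were called, against 55 of 15080 (0.365%) elsewhere, an odds ratio of 3.85 that did not pass (95% interval 0.450 to 14.8, Fisher's exact test, two-sided p = 0.101). The pair was Lmo4, a transcriptional cofactor gene 2.02 Mb upstream (ENSMUSG00000028266, chromosome 3, 144188530 to 144205220), and Gm43429, an unconfirmed transcript at 135860348 to 135862598. Lmo4 fell 1.72-fold, from 67.3 ± 3.04 to 39.2 ± 2.32 CPM (log2 fold change -0.78, SE 0.075, edgeR quasi-likelihood adjusted p = 0.000624). Gm43429, on the same strand as Slc39a8 and inside its span but outside its exons, had 24, 35 and 21 counts in WT against 3, 0 and 1 (edgeR quasi-likelihood adjusted p = 0.0136). The Gm43429 call was lost without labelled Lpar3-/- replicate 1, 2 or 3 (edgeR adjusted p = 0.0612, 0.0766 and 0.122). Without WT replicate 2 the odds ratio was 4.63 (Fisher's exact test, p = 0.0306). Without labelled Lpar3-/- replicate 1 or 3 it was 9.54 or 9.46 (Fisher's exact test, p = 0.108 and 0.109). In windows of 5, 10 and 50 Mb the odds ratio was 7.11, 3.41 and 1.59 (Fisher's exact test, p = 0.136, 0.260 and 0.368). Genes are not independent replicates, so these p-values describe the libraries at hand.

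**Figure D5:**
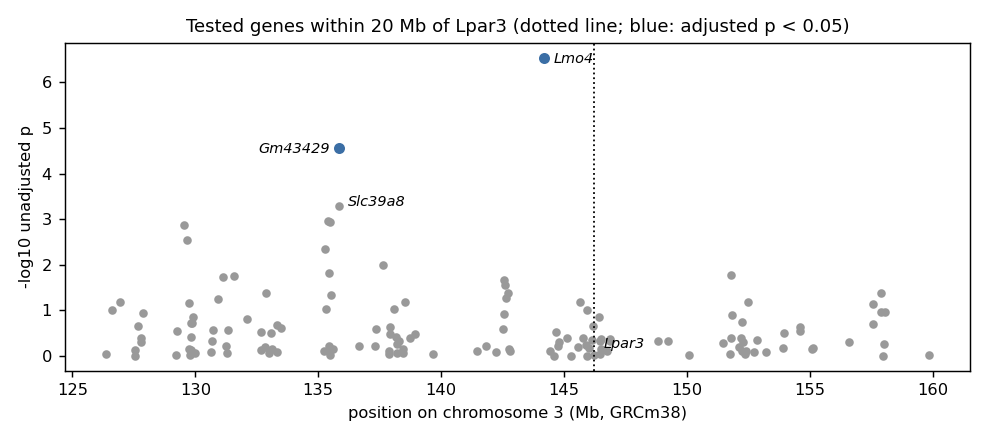
Unadjusted edgeR p, as -log10, of the tested genes within 20 Mb of Lpar3 against their position on chromosome 3 (GRCm38, Mb), each point a gene. The dotted line marks Lpar3, and the 2 blue points, Lmo4 and Gm43429, passed the adjusted threshold.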

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

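Choices other than the adipose covariate, the kept unnamed genes and the hypoxia list without Epo were fixed before the data were examined. The count of 57 genes became 171 with DESeq2 (81 higher and 90 lower), 520 without the filter on low counts (190 and 330), 9 with limma on log2(FPKM + 1), 13 with log2(FPKM + 0.1), 20 with a fold threshold of 2 and 3 with the adipose level as a covariate. It ran from 12 to 149 with 1 library left out, and from 11 to 54 of the 57 were then kept, none with a changed sign. The covariate leaves 3 residual degrees of freedom in place of 4, and the fold threshold can only lower the count. The cause of the other shifts was not tested. Limma-voom (55), RLE (58) and upper quartile scaling (57), the stricter filter (52), protein-coding genes alone (66) and unnamed genes kept (58) stayed within 1.5 times. Other scalings moved the median fold change of all genes, -0.0036, to -0.0022 or -0.0019.

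Epo was lower in all 17 alternatives. Its log2 fold change ran from -1.83 to -1.70 with 1 library left out and was -1.86 with the adipose covariate, where the adjusted p was 0.783. Over all alternatives the adjusted p ran from 3.31e-06 to 0.783. The lowest came from the fit without the filter on low counts, although the SE of Epo was larger there (0.31 against 0.26). The p-values of that fit, and so its count of 520 genes, are therefore not on the scale of the other fits. The 22 called named genes kept their sign throughout. Over all these genes and fits with 1 library left out, the call was kept 94 times and lost 38 times, and over the other alternatives kept 188 times and lost 53 times, for causes not tested. Of the 8 called in every fit with 1 library left out, Prlr, Cyp2a5 and Col8a1 passed in all 17 alternatives. Slc7a12, Cyp27b1, Gpt, Col6a6 and Lmo4 lost the call with the adipose covariate (edgeR adjusted p = 0.174, 0.432, 0.154, 0.0837 and 0.214). Cyp27b1 and Col6a6 also lost it in both FPKM fits, and Gpt with log2(FPKM + 1) (limma adjusted p = 0.0573). Lpar3 stayed uncalled, between -0.035 and 0.062 with 1 library left out, and changed sign without WT replicate 3 (-0.020), labelled Lpar3-/- replicate 1 (-0.035) or replicate 2 (-0.014). Among uncalled receptors, Lpar1 ran from -0.12 to 0.37 and Lpar4 from -0.43 to 0.22 with 1 library left out, and Lpar6 was 0.14 with the adipose covariate.

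The 18 lists became 0 with an estimated correlation, which allows for genes of a list moving together, and 2 by fry. For the loop of Henle and female lists the estimate was negative (-0.020 and -0.043). Moving together is thus not why these lost the call. With an estimated correlation camera also takes its p from the residual degrees of freedom, 4 here, which by itself raises p. How much of the loss this makes up for each list was not tested. With 1 library left out there were 13 to 24, and with the adipose covariate 15, of which 12 were shared. The covariate ended the calls of tubular injury (0.113), glycolysis (0.0840), interferon (0.930), cell cycle (0.0847), mitochondrially encoded (0.205) and adipose genes (0.635), the last being its own source. The fibroblast list changed direction without WT replicate 2 (adjusted p = 0.969, range 4.24e-07 to 0.969), and the ribosomal list without WT replicate 3 (0.750, range 2.71e-05 to 0.750). The odds ratio near Lpar3 stayed above 1 in all 11 alternatives. With 1 library left out it ran from 2.89 to 9.54, passing only without WT replicate 2 (4.63), for a cause not tested.

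Same-numbered libraries deviated with correlations across genes of 0.0026, 0.0051 and 0.051, against -0.048 to 0.040 for differently numbered ones. These values show no clear pairing by replicate number but cannot exclude one. With the replicate block 80 genes were called, Epo had an adjusted p of 0.0284, all 22 named genes kept their call, 19 lists passed and the odds ratio near Lpar3 was 2.71. Depth limits low genes most. Epo rests on 54 counts over the libraries labelled Lpar3-/-, and smaller changes could be missed, as 52.2% of 1.5-fold changes were recovered in the simulation.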

Other observations

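Tests chosen only after the result was seen were those of Y-linked genes, of segment 3 markers, of adipose marker correlation within groups, of Epo with the adipose level as a covariate, of the hypoxia list without Epo and of genes near Lpar3 at an unadjusted p, and the genes of the next paragraph were also picked then.

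The called genes that follow lie outside the naming rule. Blvra, which encodes the biliverdin reductase that acts after heme oxygenase, had a log2 fold change of -0.43 (SE 0.076, edgeR quasi-likelihood adjusted p = 0.0386). Acsl4, which loads arachidonic acid onto coenzyme A, was at -0.58 (SE 0.073, edgeR adjusted p = 0.00705). Acsf2 (0.48) and Acox3 (0.39), also enzymes that act on fatty acids, were higher, and the fixed list of mitochondrial fatty acid oxidation did not pass (camera, adjusted p = 0.948). Uroc1, an enzyme of histidine breakdown, was at 0.62 (SE 0.070, edgeR adjusted p = 0.00289), and kept its call in all 6 fits with 1 library left out. The growth factor receptor gene Erbb4 (0.50) was higher and Nrp1 (-0.49), a coreceptor for vascular growth factors, lower. Exons of Acox3 and Nrp1 overlap those of another annotated gene. All of these but Uroc1 lost the call without labelled Lpar3-/- replicate 1 (edgeR adjusted p from 0.0612 for Acsl4 to 0.184 for Blvra) or 3 (from 0.0813 for Acsl4 to 0.252 for Erbb4). All but Uroc1 and Acsl4 also lost it without labelled Lpar3-/- replicate 2 (from 0.0651 for Acsf2 to 0.233 for Acox3) or WT replicate 3 (from 0.0521 for Nrp1 to 0.104 for Acsf2). Without WT replicate 1 that of Blvra (0.0562) and without WT replicate 2 that of Erbb4 (0.0565) was lost. All directions follow the labels, which the equal Lpar3 counts leave unchecked.

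The 6 libraries were also split in other ways. Of the 10 splits, 1 called as many as 57 genes, the real one, and the highest of the others called 0 (384 to 895 at an unadjusted edgeR p under 0.05). The real split called 2 genes near Lpar3 and the highest other 0, so that 1 of 10 splits reached that number. For lists, 2 of 10 splits reached the real 18, and the highest other called 28, with WT replicates 2 and 3 and labelled Lpar3-/- replicate 2 against the rest. The other splits called 8 lists or more. With 10 splits no share can fall under 0.05.

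Most of the sex-biased kidney genes in the fixed lists leaned towards the female pattern. The exceptions were Cyp4a14 (log2 fold change -0.12) among the 3 female-higher genes and 1 of the 8 male-higher genes. Sex-biased genes outside these lists were not surveyed. With an estimated correlation neither list passed (camera, adjusted p = 0.624 for the male and 0.173 for the female list). Female animals among the libraries labelled Lpar3-/- are argued against by the 4 Y-linked genes and by at most 4 Xist counts. The mean log2 fold change of these Y-linked genes was 0.012 (SE over genes, not over libraries, 0.071). Lower androgen action is a candidate explanation. Odc1 (-0.38), Gusb (-1.04), Adh1 (-0.14) and Cyp4a12a (-0.37), androgen-induced genes, were picked after the pattern was seen but before their own values were. Their median log2 fold change was -0.38, at percentile 0.01 of 10000 random lists matched on expression. The random lists were drawn gene by gene, so the percentile makes no allowance for genes that move together. The male list lost its call with an estimated correlation (0.648). The percentile may therefore overstate how unusual the median is. None of the 4 was called (edgeR adjusted p of 0.0767 or more), and Gusb is also known to vary between mouse strains. For the male-higher genes, a smaller share of segment 3 tubule cells, where such genes are expressed, cannot be told apart from lower androgen action. The 8 other markers of that segment had a mean of -0.11 against -0.44 (exact permutation test, two-sided p = 0.143), although 6 of all 10 had a positive fold change, with a median of 0.048. The test left out the female-higher genes. Fewer such cells would not by themselves raise Prlr (log2 fold change 1.85, SE 0.12) and Slc7a12 (2.05, SE 0.19), while Cyp4a14 did not rise. Whether genotype, age, rank among cage mates or stress set the androgen state stays open and untested.

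Adipose markers ranked low, though not with an estimated correlation (camera, adjusted p = 0.559), and unequal amounts of fat carried along with the kidneys may account for it. Within groups the deviations of the 10 markers over the 6 libraries had a mean pairwise correlation of 0.708 and a lowest of -0.136, none of the list's genes being in another list. The most abundant, Pck1 (5725 against 5018 CPM) and Fabp4 (157 against 118 CPM), are also expressed by kidney tubules and endothelium, while Car3 (77.0 against 28.2 CPM) came next. The fall of Epo is not explained by such fat: with the adipose level as a covariate its log2 fold change was -1.86 (SE 0.46) against -1.77 (SE 0.26). The call ended (edgeR quasi-likelihood, adjusted p = 0.783, the highest of a range from 3.31e-06 over the alternatives, and unadjusted p = 0.00206) because the SE grew and 3 residual degrees of freedom remained, and a true difference in fat between the labelled groups stays open.

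Lpar3 counts did not differ between the groups. If both groups shared one genotype at Lpar3, its neighbours should differ no more often than other genes. Within 20 Mb, 8 of 144 (5.56%) had an unadjusted p under 0.01, against 457 of 15080 (3.03%) elsewhere. The difference did not pass (Fisher's exact test, two-sided p = 0.0856), and the window lay at percentile 95.6 of windows around other genes. A knockout allele without flanking sequence of another strain would also leave the neighbours alike. For this reason, and with so few genes, a shared genotype and a knockout allele that still gives reads cannot be told apart. Besides Lmo4 and Gm43429, Slc39a8 (1.33-fold higher, edgeR adjusted p = 0.0767) and the processed pseudogene Gm42807 (0, 4 and 4 counts in WT against 22, 15 and 16), picked after seeing their values, lie 10.3 and 10.7 Mb upstream. Cisd2 and Bdh2 (log2 fold change -0.28 for each, SE 0.065 and 0.080), likewise picked after seeing their values, were also among the 8. With Gm43429, Slc39a8 and Gm42807 they lie close together, between positions 135281221 and 135888572. The rest of the 8, Lmo4, Elovl6 and Egf, lie outside that stretch. Fisher's exact test counted clustered genes as separate and made no allowance for this. Whether sequence there differed between the groups was not tested. An allele that removes part of Lpar3 but leaves its transcript would give equal counts too, and reads per exon, not used here, would show it.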
